A study of Mus musculus with 8 samples.

How the data were processed

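RNA from whole mouse aortas was amplified and labelled with Cy3 or Cy5 (Agilent Low Input QuickAmp kit, per the labels' protocols), and 1 DHA and 1 control mouse were hybridised together on each of 8 arrays. The spots were read with Agilent Feature Extraction 10.7.3.1, array design 026655, per the file headers. The deposited intensity values used here were the median brightness of each spot and of its local background in both channels, to which the authors had applied no normalization, per the file headers and the values. The deposited files also hold intensity values that the scanner software had dye-normalized, and a log10 ratio of red over green made from them, per the file headers. A value table of the whole series holds log2 ratios from the authors. Its columns followed the log10 ratio of the scanner software with a slope of 3.32 on each array after turning, so that its scale is log2 and its direction DHA over control, with no centring beyond that of the software. The column medians were 0 on replicates 1 to 5, -0.02 on replicates 6 and 7 and -0.01 on replicate 8.

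The design was taken from the labels. DHA is the label's own abbreviation and was not spelled out there, and the composition of the diets was not given in the sources used here. The direction of each ratio was taken from the dyes in the labels, and each was turned to DHA over control. The description counts 8 biological replicates per group, while the sample labels name 5 control mice, and the labels were followed. Replicate numbers here name arrays. Slides were read from the array positions that come with the files. Slide 1 held replicates 2, 3, 5 and 8, slide 2 held replicates 1, 6 and 7, and slide 3 held replicate 4.

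Background was corrected by normexp with an offset of 50 (limma 3.58.1 in R 4.3.3), and loess was run within arrays with control spots at weight 0 and no scaling between arrays. The files hold no mean signal, so the median signal was used instead. Local backgrounds that the software marked as outliers, or that exceeded 1.5 times the array's median background, were replaced by that median, which concerned 2 to 45 spots per array. This repair was chosen after the unrepaired fit had been seen, and the unrepaired values are among the alternatives. The software's mark for spots well above background was set for all 43020 spots of each array that are not controls and carried no information. A spot was instead taken as detected if its signal exceeded the mean of the array's 153 negative control spots by 2.6 SD. Spots of a probe were averaged, control spots and outlier spots were left out, and saturated spots were kept. Probes were kept if detected in at least 1 channel on at least 4 arrays, which left 30430 of 39429.

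Probes were named through the accessions in the files and a RefSeq gene table of assembly GRCm38.p6. The file headers name build mm9, so that no coordinates are printed. Of the 39429 probes 26581 matched 1 gene symbol (20144 symbols) and 12848 had none. A gene was represented by its brightest probe, and a probe with no symbol stood for itself, which gave 25055 features, 16711 of them with a symbol. Of the named genes 29 had several probes kept, and in 7 of these (Cd4, Fdft1, Itgam, Ncam1, Rpl7, Rps3 and Serpinf1) the probes differed in sign.

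DHA and control aorta were compared with limma (lmFit and eBayes, two-sided) on the log2 ratios, with a term for dye orientation and control mouse as a random block. The consensus correlation of arrays that share a control mouse was -0.142 and was therefore set to 0. P-values were adjusted by Benjamini-Hochberg and tested at 0.05. The fit had 6 residual degrees of freedom and 1.87 prior degrees of freedom. The 36 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. Values of lists are medians over the members measured, 651 genes in all. Correlations between list medians over the 8 arrays were tested with exact two-sided permutation tests.

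The named genes were, per direction, up to 15 with the largest ratio among those past the threshold and of the same sign on all 8 arrays, filled to 10 with the smallest unadjusted p among genes of the same sign on at least 7 of 8 arrays. Since none passed, all 20 came from the second part of the rule. From each list up to 3 members with the smallest p were named, or up to 4 where members passed over all genes, and Ldlr was named as the gene the strain lacks. The groups, the lists, the test, the rule for named genes and most alternatives were fixed before the data were examined. No level was given as a bound for a gene below the negative controls, since the genes named by value were measured in part of both groups' channels.

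The gene test and the list test were tested on simulated data with the real design and the 24965 features that had a value on all 8 arrays. With known changes put in, the test recovered 58% of genes changed by a log2 ratio of 0.5, 82% at 1, 98% at 2 and 94% at 3, and it called 0.0485% of the unchanged genes. A list of 20 shifted genes was called and 0 other lists were, with camera at the preset correlation. The simulated genes varied independently of each other. In the real lists the estimated correlation between genes ran from 0.009 (vasoactive genes) to 0.94 (erythroid genes). The simulation therefore says nothing about false list calls among genes that vary together. The alternatives tried were other treatments of the control mouse, the dye and the slide, other backgrounds (none, an offset of 16, or as deposited), the software's own signals, median centring in place of loess, equal scale between arrays, a separate-channel fit after Aquantile, other filters and probe rules, array weights, an intensity trend, the authors' value table, each array left out in turn, the arrays of either shared control mouse left out, a fixed correlation of 0.5, replicates 1 and 7 left out, and features saturated on any array (145) left out.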

Results

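Gene expression was measured in the whole aorta, from the aortic root to the iliac bifurcation, of male C57BL mice that lack the low density lipoprotein receptor (LDLR), the receptor that clears LDL from plasma and whose loss lets atherosclerotic plaques form in mice. The mice were 28 weeks old and had been on a dietary intervention for 20 weeks, and the comparison asks how aortas of the group labelled DHA differed from those of the control group. The data are 8 two-colour arrays, and each held the labelled RNA of 1 DHA mouse and 1 control mouse. The labels name 8 DHA mice and 5 control mice. One control mouse was on 3 arrays (replicates 1, 2 and 8), another on 2 arrays (replicates 5 and 7), and the other control mice on 1 array each. DHA was labelled with Cy5 on 5 arrays and with Cy3 on 3 arrays (replicates 1, 4 and 5). Between 61.1% and 67.1% of the 39429 probes were above the negative controls in the green channel of an array, and between 67.4% and 81.3% in the red channel. The number of arrays limits the precision of every value below. The only probe of Ldlr was above the negative controls in the DHA channel of 3 arrays and in the control channel of 2, and the sources used here do not say whether it lies in the deleted part of the gene.

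No single gene passed the test for a difference between DHA and control aorta. Of 25055 genes and unnamed features tested with limma, 0 passed an adjusted p of 0.05 in either direction, and the smallest adjusted p was 0.404. At an unadjusted p under 0.05 there were 1991 features, 1161 higher and 830 lower in DHA aorta, where 1253 would be expected by chance, and without replicate 1 there were 1242. All genes named in the next paragraph had the same sign on at least 7 of the 8 arrays and did not pass the threshold, and errors are moderated standard errors from the fit with a dye term. Here and below, counts of arrays take replicate 8 as labelled, although its labels were less clear than others. With that array turned, its ratios would change sign.

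The gene with the largest ratio among the 10 leading higher genes was Gsta3, a glutathione S-transferase, at a log2 ratio of 0.97 ± 0.20 (1.96-fold, adjusted p = 0.590). It was above 0 on 8 of 8 arrays as labelled (1.36 on replicate 8). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, had a log2 ratio of 0.68 ± 0.10 (1.60-fold, adjusted p = 0.404) and was higher on 7 of 8 arrays. Cebpb, a transcription factor of adipocyte and myeloid differentiation, was at 0.49 ± 0.10. The ratio of Polr3gl, a subunit of RNA polymerase III, was small but varied little between mice, at 0.28 ± 0.03 with an SD of 0.07 over the arrays (adjusted p = 0.404). Lrrc45, a centrosome protein, was at 0.48 ± 0.10, and Phka2, a regulatory subunit of phosphorylase kinase, at 0.39 ± 0.08. Ankzf1 was at 0.35 ± 0.07, Klhl2 at 0.28 ± 0.05, Szt2 at 0.25 ± 0.05 and Elac2, an enzyme of tRNA 3′ end processing, at 0.21 ± 0.04. On the lower side, Dbp, a transcription factor driven by the circadian clock, had a log2 ratio of -0.74 ± 0.11 (adjusted p = 0.404) and was lower on 7 of 8 arrays. Rnd3, a Rho family GTPase, was at -0.62 ± 0.11, and Rspo3, a secreted enhancer of Wnt signalling, at -0.51 ± 0.07. Both were lower on 8 of 8 arrays as labelled (-0.94 and -0.71 on replicate 8). Mthfd1l, an enzyme of mitochondrial folate metabolism, was at -0.48 ± 0.06 and Ngef, a Rho guanine nucleotide exchange factor, at -0.48 ± 0.06. Atf7ip was at -0.35 ± 0.06, Calml4 at -0.31 ± 0.04, Bace1, the beta-secretase, at -0.30 ± 0.04, Wfikkn2 at -0.29 ± 0.04 and Pcdh18 at -0.25 ± 0.04. Other probes that were kept gave smaller ratios for Polr3gl (0.06), Phka2 (0.01), Gsta3 (0.56), Mthfd1l (-0.15) and Wfikkn2 (-0.07 and -0.22), and -0.78 for Dbp. None of these 20 genes changed sign under any of the 34 other settings tried, and none passed the threshold in any of them. They were picked from the same data for a steady sign and a small p, so that a kept sign is no independent support.

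**Figure D1:**
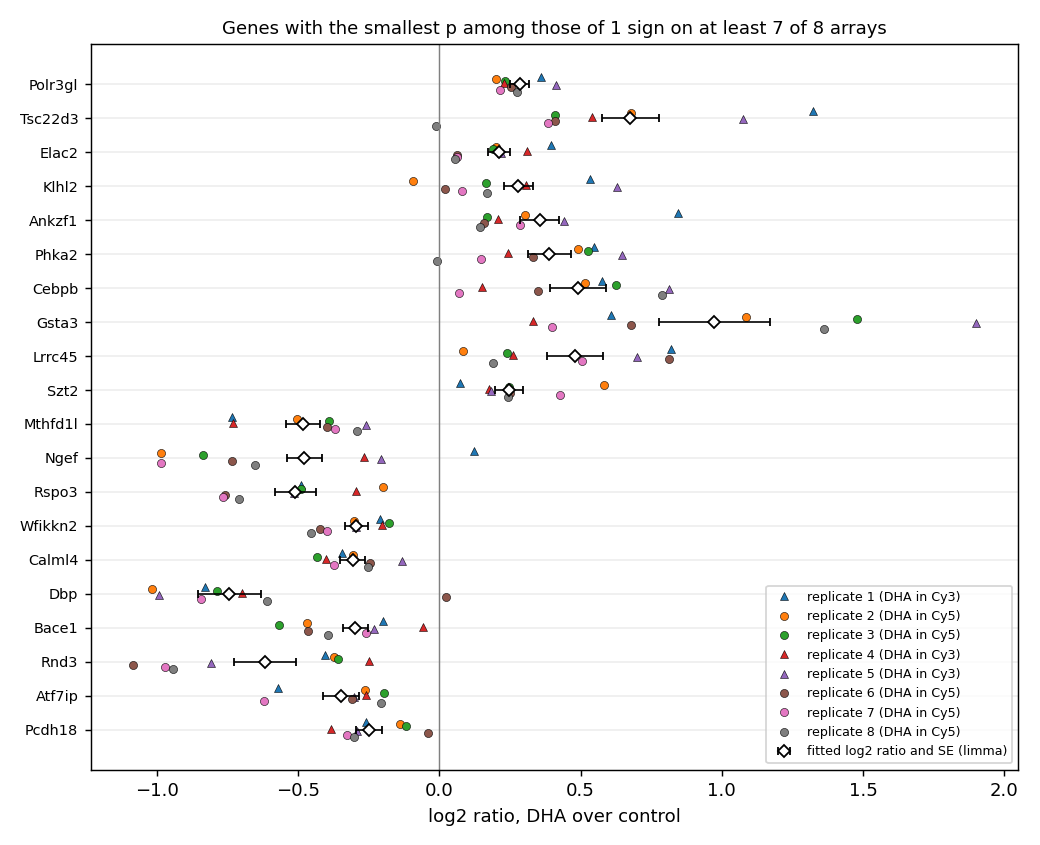
Log2 ratio of DHA over control aorta (x axis) for the 10 higher and 10 lower genes named by the fixed rule (y axis). Coloured points are the 8 arrays, circles with DHA in Cy5 and triangles with DHA in Cy3; white diamonds with bars are the fitted log2 ratio and its SE. Gsta3 spans 0.33 to 1.90 on single arrays, while the values of Polr3gl lie between 0.20 and 0.41.

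Sets of related genes were compared using 36 lists of pathway genes and cell type markers. With limma's camera and its preset correlation of 0.01 between genes, 16 of the 36 lists differed from all other genes at an adjusted p of 0.05, 11 towards lower and 5 towards higher values in DHA aorta. With a correlation estimated from the data, camera called 0 of the 36 lists, and 0 had an unadjusted p under 0.05. The fry test of limma, which asks whether a list's genes move one way on balance, called 0 lists, and 1 list, mast cells and neutrophils, had an unadjusted p under 0.05. No member of any list passed over all genes tested. Adjusted over the list alone, 5 members passed, namely Actg2 among contractile smooth muscle genes, Tie1 among endothelial genes, Dbp among clock genes, and Plat and Serpine2 among coagulation genes. Under the setting with slide as a block 16 lists passed. Within slide 1 (4 arrays) 11 passed and within slide 2 (3 arrays) 20 passed. Slide 3 held 1 array, replicate 4, which gave no value of its own and carried no weight with slide as a block. Slides 1 and 2 each held 1 array with DHA in Cy3, replicate 5 on slide 1 and replicate 1 on slide 2. With the dye term, that array weighed as much as the slide's other arrays together. The values within a slide thus rest largely on these arrays. The lists are given below with the median log2 ratio of their members. Members of a list can vary together, so that a count of members does not show how many arrays share a sign.

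By the median of the fitted ratios, collagens and elastic matrix genes were the lowest of the lists that passed, while by the mean of the members (-0.29) they stood behind antigen presentation genes (-0.30). Of 24 measured collagens and elastic matrix genes, 22 were lower in DHA aorta, with a median log2 ratio of -0.35 and a camera adjusted p of 5.19e-08 (adjusted p = 0.538 with an estimated correlation). The median was below 0 on 7 of 8 arrays as labelled (-0.07 on replicate 8). It was -0.19 within slide 1, -0.54 within slide 2 and -0.41 with slide as a block. Fn1, which encodes fibronectin and was saturated on 2 arrays, was at -0.60 ± 0.20, Col18a1 at -0.39 ± 0.12 and Col4a2, a basement membrane collagen, at -0.39 ± 0.12. Coagulation and fibrinolysis genes had a median of -0.18, with 12 of 14 lower (camera adjusted p = 0.00138; adjusted p = 0.538 with an estimated correlation). In that list Serpine2, a protease inhibitor, was at -0.73 ± 0.20 and Plat, the tissue plasminogen activator, at -0.38 ± 0.09. Both were below 0 on 8 of 8 arrays as labelled (-0.31 and -0.29 on replicate 8), whereas F13a1 was at 0.52 ± 0.22. Of 22 matrix proteases and inhibitors 18 were lower, with a median of -0.14 (camera adjusted p = 0.00998; adjusted p = 0.670 with an estimated correlation). On single arrays the protease median was below 0 on 4 and above 0 on 4 (-0.84 to 0.66). Timp2, saturated on 1 array, was at -0.41 ± 0.12, Timp3 at -0.20 ± 0.09 and Mmp2 at -0.38 ± 0.25. Cartilage and bone genes had a median of -0.10, with 11 of 16 lower (camera adjusted p = 0.0297; adjusted p = 0.538 with an estimated correlation). Among them Acan was at -0.35 ± 0.12, Bmp2 at -0.26 ± 0.10 and Ibsp at 0.17 ± 0.09. Within slide 1, within slide 2 and with slide as a block, the medians were -0.09, -0.21 and -0.19 for coagulation genes, 0.01, -0.41 and -0.15 for matrix proteases, and -0.06, -0.12 and -0.11 for cartilage genes. The protease list did not pass without replicate 1 (median -0.01), 2 (-0.04) or 7 (-0.07) and stood at -0.23 without replicate 5. The cartilage list did not pass without replicate 1 (-0.05), 5 (-0.09) or 7 (-0.07) and stood at -0.05 without replicate 2. The coagulation median was -0.12 without replicate 7. The protease list also did not pass within slide 1, with array weights (-0.02), with the authors' value table (-0.20), without the 3 arrays of control mouse K25 (0.06), with the fixed correlation (-0.04) or without replicates 1 and 7 (0.05). Other settings in which the cartilage list did not pass were slide 1, the software's own signals (-0.14), the authors' value table (-0.14), every probe on its own (-0.05), and leaving out control mouse K93 (-0.05) or replicates 1 and 7 (-0.03). The coagulation list did not pass within slide 1 or without replicates 1 and 7 (-0.07). Without the genes saturated on any array the protease list did not pass (-0.05, 17 genes), while the collagen list (-0.35, 21 genes) and the coagulation list (-0.22, 13 genes) passed. Mgp and Sparc among the collagen and matrix genes were saturated on 7 arrays, in both channels on 2 and 3 of them. F10 among the coagulation genes was saturated in both channels on 8 arrays. The ratios of these genes cannot be read as differences, and on single arrays those of Mgp ran from -0.64 to 0.90.

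Markers of the resident cells of the vessel wall, immediate early genes and cell cycle genes were also shifted towards lower values. Of 20 contractile smooth muscle genes 13 were lower, with a median of -0.15 (camera adjusted p = 0.00439; adjusted p = 0.597 with an estimated correlation). Of these genes Acta2, Tagln, Myl9 and Csrp1 were saturated in at least 1 channel on all 8 arrays. Acta2, Tagln and Myl9 shared a ratio of 1.41 on replicate 2. With Csrp1 they shared 1.21 on replicate 6 and -0.50 on replicate 8, so that these ratios cannot be read as differences. Cnn1 was saturated in 1 channel on 3 arrays, where a difference would be compressed. Among the 15 members saturated on no array 12 were lower, with a median of -0.18, and the list passed. Actg2, an enteric-type smooth muscle actin, was at -0.46 ± 0.10, Kcnmb1, a subunit of the large-conductance potassium channel, at -0.34 ± 0.12, and Tpm2 at -0.33 ± 0.11. Endothelial genes had a median of -0.11 and a mean of -0.03, with 13 of 18 lower and 5 higher (camera adjusted p = 0.0212; adjusted p = 0.670 with an estimated correlation). Tie1, an endothelial receptor kinase, was at -0.46 ± 0.10 and lower on 8 of 8 arrays, Pecam1 was at -0.30 ± 0.08 and Tek, the angiopoietin receptor, at -0.29 ± 0.10. Immediate early genes had a median of -0.09, with 14 of 18 lower (camera adjusted p = 0.00138; adjusted p = 0.538 with an estimated correlation), including Ccn1 at -0.79 ± 0.25, Egr1 at -0.59 ± 0.20 and Fosb at -0.57 ± 0.14. Cell cycle genes had a median of -0.19, with 17 of 19 lower (camera adjusted p = 4.01e-06; adjusted p = 0.538 with an estimated correlation). Mcm6, a subunit of the replicative helicase, was at -0.28 ± 0.09, Mcm5 at -0.20 ± 0.09, and Top2a, above the negative controls in the DHA channel of 2 arrays and the control channel of 5, at -0.17 ± 0.07. Within slide 1, within slide 2 and with slide as a block, the medians were -0.16, -0.07 and -0.16 for smooth muscle genes, -0.27, 0.06 and -0.11 for endothelial genes, -0.08, -0.19 and -0.11 for immediate early genes, and -0.07, -0.41 and -0.22 for cell cycle genes. Endothelial genes did not pass with slide as a block, nor with arrays that share a control mouse averaged (median -0.11), nor without replicate 2 (median -0.12), 3 (-0.06), 4 (-0.11) or 5 (-0.08), and stood at -0.18 without replicate 1 and -0.19 without replicate 6. Smooth muscle genes did not pass without replicate 5 (-0.12) or 8 (-0.14), the immediate early median ran from -0.06 without replicate 7 to -0.16 without replicate 3 and -0.17 without replicate 8, and the cell cycle median was -0.08 without replicate 1. Calls were also lost within slide 1 for cell cycle genes and within slide 2 for smooth muscle and endothelial genes. Without the 2 arrays of control mouse K93 they were lost for smooth muscle (-0.08), endothelial (-0.04) and immediate early genes (-0.08). The same held with the local backgrounds as deposited for endothelial genes (-0.10), and without replicates 1 and 7 for cell cycle genes (-0.05).

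Among immune genes, the interferon and antigen presentation lists were shifted towards lower values. Interferon response genes had a median log2 ratio of -0.16, with 15 of 18 lower (camera adjusted p = 9.02e-05; adjusted p = 0.538 with an estimated correlation). On single arrays the interferon median was below 0 on 5 and above 0 on 3 (-0.52 to 0.17). The guanylate-binding protein genes Gbp2 and Gbp3 were at -0.53 ± 0.16 and -0.55 ± 0.18, and Irf9 was at -0.20 ± 0.10. Antigen presentation genes had a median of -0.29, with 15 of 19 lower (camera adjusted p = 2.38e-05; adjusted p = 0.597 with an estimated correlation). The antigen presentation median was below 0 on 5 arrays and above 0 on 3 (-1.03 to 0.51). Tap1, a subunit of the peptide transporter for MHC class I loading, was at -0.22 ± 0.07, Tapbp at -0.28 ± 0.10 and Psmb8, an immunoproteasome subunit, at -0.44 ± 0.19. Leukocyte adhesion genes had a median of -0.22, with 14 of 18 lower (camera adjusted p = 0.00294; adjusted p = 0.538 with an estimated correlation). The leukocyte adhesion median was below 0 on 6 arrays and above 0 on 2. Selp, which encodes P-selectin, was at -0.38 ± 0.16, Esam at -0.29 ± 0.13 and Sell at -0.22 ± 0.11. Within slide 1, within slide 2 and with slide as a block, the medians were -0.19, -0.21 and -0.20 for interferon response genes, -0.23, -0.36 and -0.31 for antigen presentation genes, and -0.06, -0.34 and -0.23 for leukocyte adhesion genes. Without replicate 1 the interferon median was -0.09 and the leukocyte adhesion median -0.07, and the latter was -0.12 without replicate 2 and -0.14 without replicate 7. Leukocyte adhesion genes did not pass within slide 2, without the 2 arrays of control mouse K93 (-0.13) or without replicates 1 and 7 (-0.05). Antigen presentation genes did not pass without the 3 arrays of control mouse K25 (-0.16) or without replicates 1 and 7 (-0.13).

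Macrophage and foam cell genes did not pass as a list, and they differed more between mice than those of most lists. Of 23 measured members 19 had a log2 ratio below 0, with a median of -0.34 (camera adjusted p = 0.0686). On single arrays the list's median ran from -2.13 on replicate 2 to 1.92 on replicate 6, with an SD of 1.48. It was below 0 on 5 arrays and above 0 on 3 as labelled, or 6 and 2 if the labels of replicate 8 (0.76), which were less clear than others, are turned. Within slide 1 it was 0.20, within slide 2 it was -0.59 and with slide as a block it was -0.23. The list passed towards lower values without replicate 5 (median -0.73), 6 (-0.67) or 8 (-0.46), within slide 2, without a dye term (-0.35), with the local backgrounds as deposited (-0.32), with arrays that share a control mouse averaged (-0.34), with an offset of 16 (-0.36), with an intensity trend (-0.34) and without the 2 arrays of control mouse K93 (-0.54). Averaging arrays that share a control mouse weighted each mouse by its number of arrays. Its medians therefore equal the main ones by construction and do not check the reuse of control mice. Without replicate 1 the list's median was 0.06, and without the 3 arrays of control mouse K25 it was 0.06. Gpnmb, a glycoprotein of lipid-laden macrophages, was at -1.24 ± 0.86, Lgals3, which encodes galectin-3 and was saturated on 1 array, at -0.81 ± 0.68, and Itgam, the integrin CD11b, at 0.28 ± 0.11 by its brightest probe, while its 2 other probes were at -0.00 and 0.08. The lists of antigen presentation and of matrix proteases contain genes that macrophages express. Over the 8 arrays the antigen presentation median followed the macrophage median (Pearson r = 0.98, exact permutation p = 4.96e-05, and Spearman rho = 1, exact permutation p = 4.96e-05, the smallest that permuted ranks can give). Without the 2 arrays farthest from the macrophage median r was 0.95, and over the 11 relations between list medians that were computed the adjusted p was 5.46e-04. The medians of leukocyte adhesion genes (Pearson r = 0.88, exact permutation p = 0.00662; Spearman rho = 0.90, exact permutation p = 0.00456; r = 0.92 without those 2 arrays; adjusted p = 0.0182) and of matrix proteases (Pearson r = 0.89, exact permutation p = 0.00608; Spearman rho = 0.86, exact permutation p = 0.0107; r = 0.94 without those 2 arrays; adjusted p = 0.0182) also followed it over the 11 relations. These 2 relations were chosen after the others had been seen. The macrophage median was also set against those of cell cycle genes (Pearson r = 0.76, exact permutation p = 0.0375; Spearman rho = 0.71, exact permutation p = 0.0576; r = 0.80 without the 2 arrays farthest from the macrophage median; adjusted p = 0.0590 over the 11 relations) and of collagens (Pearson r = 0.66, exact permutation p = 0.0679; Spearman rho = 0.76, exact permutation p = 0.0368; r = 0.65 without those 2 arrays; adjusted p = 0.0830), neither of which passed over the 11 relations. Against contractile smooth muscle genes, some of them saturated, Pearson r was -0.67 (exact permutation p = 0.0586; Spearman rho = -0.67, exact permutation p = 0.0831; r = -0.81 without those 2 arrays; adjusted p = 0.0805 over the 11 relations). Against fatty acid oxidation genes it was 0.02 (exact permutation p = 0.961; Spearman rho = 0.14, exact permutation p = 0.752; r = -0.31 without those 2 arrays; adjusted p = 0.961 over the 11 relations). No value within a slide is given, since no slide held more than 4 arrays. Here and below, the permutations treat the 8 arrays as independent, although some share a control mouse. The p-values of these relations may therefore be too small.

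Lipid catabolism and fat cell genes were shifted towards higher values. Of 28 fatty acid oxidation and PPAR-alpha target genes 25 were higher in DHA aorta, with a median log2 ratio of 0.37 (camera adjusted p = 4.00e-06; adjusted p = 0.538 with an estimated correlation). The list's median was above 0 on 7 of 8 arrays as labelled (0.23 on replicate 8). Angptl4, an inhibitor of lipoprotein lipase, was at 0.94 ± 0.21 and Pex11a, a peroxisome proliferation factor, at 0.43 ± 0.11, both above 0 on 8 of 8 arrays. Pdk4, a kinase that restrains glucose oxidation, was at 1.07 ± 0.33. All 17 adipocyte genes had a ratio above 0, with a median of 0.30 (camera adjusted p = 4.09e-04; adjusted p = 0.597 with an estimated correlation). On single arrays the adipocyte median was above 0 on 6 and below 0 on 2 (-0.79 to 1.40). Fabp4, the fatty acid-binding protein of adipocytes and macrophages, was at 1.08 ± 0.41, Acvr1c at 0.46 ± 0.15 and the triglyceride lipase gene Pnpla2 at 0.26 ± 0.11. Brown adipocyte genes had a median of 0.34, with 13 of 15 higher (camera adjusted p = 0.0212; adjusted p = 0.670 with an estimated correlation). The brown adipocyte median was above 0 on 6 arrays and below 0 on 2 (-0.72 to 1.61). Examples of these genes were Slc27a2 at 0.79 ± 0.42, Ebf2 at 0.51 ± 0.13 and Kcnk3 at 0.34 ± 0.16. Within slide 1, within slide 2 and with slide as a block, the medians were 0.24, 0.97 and 0.59 for fatty acid oxidation genes, 0.80, 0.52 and 0.56 for adipocyte genes, and 0.11, 1.12 and 0.71 for brown adipocyte genes. Without replicate 1 the fatty acid oxidation median was 0.11 and the brown adipocyte list did not pass and turned direction in the test (median 0.02), and without replicate 5 the adipocyte list did not pass (0.18). The brown adipocyte list also did not pass within slide 1, without the 3 arrays of control mouse K25 (0.11), with array weights (0.09), with equal scale between arrays (0.24), in the separate-channel fit (0.34), with both channels above background on all 8 arrays (0.33) or without replicates 1 and 7 (-0.02). The adipocyte list did not pass without the 2 arrays of control mouse K93 (0.20). Without replicate 4 these medians were 0.60, 0.55 and 0.70 for fatty acid oxidation, adipocyte and brown adipocyte genes. The median of the fatty acid oxidation list followed the mean of the 2 fat cell list medians over the 8 arrays (Pearson r = 0.91, exact permutation p = 0.00258; Spearman rho = 0.95, exact permutation p = 0.00114; r = 0.89 without the 2 arrays farthest from the median of the fat cell lists; adjusted p = 0.0142 over the 11 relations). The collagen median was set against the same mean and did not pass (Pearson r = -0.34, exact permutation p = 0.412; Spearman rho = -0.40, exact permutation p = 0.327; r = 0.16 without those 2 arrays; adjusted p = 0.453 over the 11 relations).

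Mitochondrial and muscle gene lists had their largest ratios on replicate 1. All 27 oxidative phosphorylation genes had a ratio above 0, with a median of 0.23 (camera adjusted p = 4.00e-06; adjusted p = 0.597 with an estimated correlation). On single arrays the list's median was above 0 on 5 and below 0 on 3 (-0.24 to 1.15). The list did not pass without replicate 1 (median 0.06) or with median centring in place of loess (0.02), and without replicate 4 its median was 0.38. Cox7b was at 0.39 ± 0.13, Cox5b at 0.29 ± 0.11 and Ndufb5 at 0.20 ± 0.08, the last of these turning to -0.02 with median centring in place of loess. The list's median followed the fat cell list medians over the 8 arrays (Pearson r = 0.78, exact permutation p = 0.0221; Spearman rho = 0.81, exact permutation p = 0.0218; r = 0.71 without the 2 arrays farthest from the median of the fat cell lists; adjusted p = 0.0405 over the 11 relations). Against the muscle list median it had a Pearson r of 0.89 (exact permutation p = 0.0112; Spearman rho = 0.71, exact permutation p = 0.0576; adjusted p = 0.0246 over the 11 relations), which rested on the 2 arrays farthest from the muscle median, since r was 0.41 without them. Of 18 skeletal and cardiac muscle genes 16 were higher, with a median of 0.37 (camera adjusted p = 0.00393; adjusted p = 0.597 with an estimated correlation). Their median was 1.46 on replicate 1 and at most 0.12 on the other arrays, and without replicate 1 the list did not pass (median 0.05). Ryr2, the cardiac calcium release channel, was at 0.36 ± 0.18, Tnnt3 at 0.27 ± 0.12 and Acta1 at -0.33 ± 0.11. Within slide 1, within slide 2 and with slide as a block, the medians were 0.07, 0.71 and 0.37 for oxidative phosphorylation genes and 0.03, 0.70 and 0.45 for muscle genes. Neither list passed within slide 1 or without replicates 1 and 7 (0.03 and 0.05), and the muscle list did not pass without the 3 arrays of control mouse K25 (0.08).

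**Figure D2:**
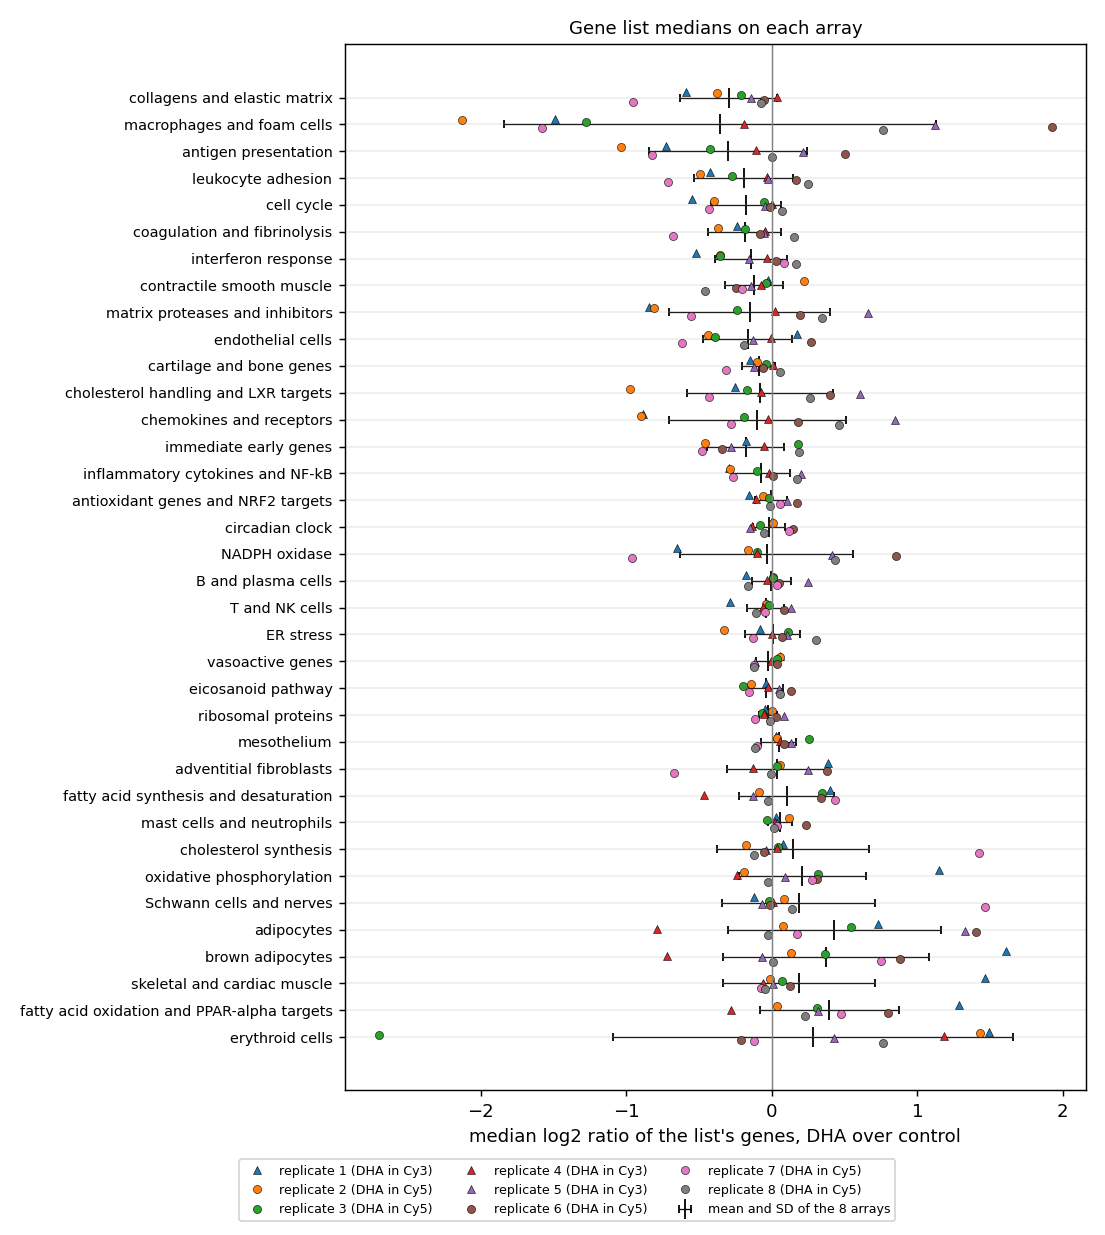
Median log2 ratio of DHA over control aorta (x axis) of each of the 36 gene lists (y axis, ordered by the median of the fitted ratios). Coloured points are the 8 arrays, circles with DHA in Cy5 and triangles with DHA in Cy3; ticks with bars are the mean and SD of the 8 arrays. The macrophage list spans -2.13 to 1.92, and the muscle list stands at 1.46 on replicate 1.

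The other 19 lists did not pass. Inflammatory cytokines and NF-kB genes had a median log2 ratio of -0.06 (camera adjusted p = 0.0678), in which Nfkbia, an inhibitor of NF-kB, was at 0.51 ± 0.19, Il18 at 0.21 ± 0.08 and Rela at -0.14 ± 0.06. T and NK cell genes were at -0.03 (adjusted p = 0.0658), with Gzma, a granzyme of cytotoxic lymphocytes, at -0.43 ± 0.11. Mast cell and neutrophil genes were at 0.08 (adjusted p = 0.0678), with the mast cell tryptase gene Tpsb2 at 0.18 ± 0.07 and the histidine decarboxylase gene Hdc at 0.18 ± 0.07. B and plasma cell genes were at -0.03 (adjusted p = 0.286) and chemokines and their receptors at -0.09 (adjusted p = 0.222), with Ccl11 at 0.33 ± 0.13, Ccr7 at -0.35 ± 0.17 and Cxcl10 at -0.39 ± 0.20. Circadian clock genes were at -0.04 with an adjusted p of 0.0649. By fry's mixed test, which asks for a difference in either direction, members of that list differed from 0 (adjusted p = 0.00829), with Nr1d1 at -0.34 ± 0.13 besides Dbp. Cholesterol synthesis genes had a median of 0.12 (adjusted p = 0.222), with 18 of 19 above 0, and the median was -0.00 without replicate 7, where it stood at 1.42. Cholesterol handling and LXR target genes were at -0.09 (adjusted p = 0.510), although Apoc1 was at 0.84 ± 0.35. Fatty acid synthesis and desaturation genes were at 0.08 (adjusted p = 0.297), with the transcription factor gene Mlxipl at 0.57 ± 0.15 and Acacb, an acetyl-CoA carboxylase, at 0.64 ± 0.23. Antioxidant genes and NRF2 targets were at -0.04 (adjusted p = 0.671), and among them Sod3, the extracellular superoxide dismutase, was at -0.35 ± 0.10 and Gpx4 at 0.21 ± 0.06, which turned to -0.01 with median centring in place of loess. Eicosanoid pathway genes were at 0.01 (adjusted p = 0.701), with the prostaglandin E receptor genes Ptger3 and Ptger4 at -0.25 ± 0.10 and -0.16 ± 0.06 and the leukotriene C4 synthase gene Ltc4s at 0.36 ± 0.15. NADPH oxidase genes were at -0.04 (adjusted p = 0.464). ER stress genes were at -0.03 (adjusted p = 0.464), with Trib3 at 0.29 ± 0.11 and Calr at -0.21 ± 0.07.

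Markers of tissue that surrounds or perfuses the aorta were also measured. Adventitial fibroblast genes had a median of 0.04 (adjusted p = 0.175), with Entpd2 at 0.30 ± 0.10 and above 0 on 8 of 8 arrays. Schwann cell and nerve genes were at 0.26 (adjusted p = 0.409) and at 0.00 without replicate 7, where the median was 1.47, with Plp1, the myelin proteolipid protein gene, at 0.59 ± 0.42. Mesothelial genes were at 0.04 (adjusted p = 0.384), erythroid genes at 0.43 (adjusted p = 0.222; 4 genes), vasoactive genes at 0.01 (adjusted p = 0.286) and ribosomal protein genes at 0.02 (adjusted p = 0.686). In the antioxidant, eicosanoid, ER stress, vasoactive and ribosomal protein lists the median, the mean and the direction of the test did not share a sign. Within slide 1 chemokines passed towards higher values (median 0.33) and clock genes towards lower values (-0.08). Within slide 2 lower values passed for chemokines (-0.52), inflammatory genes (-0.24), T and NK cell genes (-0.11) and B cell genes (-0.03), and higher values for erythroid genes (0.59) and fatty acid synthesis genes (0.45). Fatty acid synthesis genes also passed with slide as a block (0.23) and without replicate 4 (0.22), but stood at -0.06 without replicate 1 and -0.01 within slide 1. Leaving out replicate 5 brought chemokines (-0.36), inflammatory genes (-0.10), T and NK cell genes (-0.11) and B cell genes (-0.07) past the threshold, whereas without replicate 1 none of these passed and the medians were 0.16, 0.02, 0.01 and 0.01. Leaving out replicate 6 did so for chemokines (-0.11), inflammatory genes (-0.07), T and NK cell genes (-0.05), clock genes (-0.05) and cholesterol handling genes (-0.18). Clock genes also passed without replicate 1 (-0.06) or 2 (-0.07), inflammatory genes (-0.11) and mast cell genes (0.06) without replicate 8, erythroid genes without replicate 3 (0.73), and adventitial genes without replicate 7 (0.09). With arrays that share a control mouse averaged, inflammatory genes (-0.06) and mast cell genes (0.08) passed, at medians equal to the main ones by construction. Without the 3 arrays of control mouse K25 chemokines (0.17), cholesterol synthesis genes (0.23), mast cell genes (0.11) and clock genes (-0.09) passed. Without control mouse K93 lower values passed for chemokines (-0.24), inflammatory genes (-0.09), T and NK cell genes (-0.10) and B cell genes (-0.07). With the local backgrounds as deposited, chemokines (-0.19), inflammatory genes (-0.09) and T and NK cell genes (-0.06) passed towards lower values. Ribosomal protein genes passed towards lower values with the scanner software's own signals (-0.07), with the authors' value table (-0.07) and with median centring in place of loess (-0.21), and the latter also brought clock genes (-0.15), antioxidant genes (-0.21) and mast cell genes (0.06) past the threshold. Smaller changes of method also carried some of these lists past it. An offset of 16 and an intensity trend did so for inflammatory and T and NK cell genes, and no dye term for inflammatory genes. Equal scale, array weights, the stricter filter and the fixed correlation did so for clock genes. Taking every probe on its own did so for these 3 lists and for mast cell genes.

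The arrays' own controls bear on the scale of the ratios. The slope of observed against expected log ratios of the spike-in RNAs, per the file headers, was between 0.840 and 0.898 on the 8 arrays. The scanner software's own ratios were thus compressed, while the slope for the ratios reported here was not measured. For genes given with values that were below the negative-control limit in some channels, the numbers of DHA and control channels above it were 7 and 8 for Ccl11, Ccr7, Hdc and Zap70, 5 and 6 for Cxcl10 and Sell, 7 and 6 for Acvr1c, 8 and 7 for Ebf2, 6 and 5 for Fcmr, and 5 and 5 for Pou2af1, besides Top2a above. The dye term passed an adjusted p of 0.05 for 56 of the 25055 features. The log2 ratios of 2 arrays correlated, across genes, between -0.42 and 0.48, with a median of 0.02 over the 28 pairs, and the lowest correlation between arrays of like dye orientation was -0.16.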

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

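None of the values here comes from a test chosen after the results were seen. In each set of 8 arrays, the highest or lowest value was compared with its nearest neighbour, and the gap was set against the range of the set (Dixon's criterion at its critical value for 8 values). Of 167 sets, 17 exceeded the limit, where 8.35 would be expected by chance.

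On replicate 1, the median log2 ratio of the skeletal and cardiac muscle list was 1.46, and the nearest of the other arrays was at 0.12. Ryr2 was at 1.90 on that array and at most 0.31 on the others. The oxidative phosphorylation median was 1.15 there (nearest 0.32), with Cox5b at 1.08 (nearest 0.26). Pdk4 was at 3.30 (nearest 1.35), Nfkbia at 1.68 (nearest 0.67) and Ankzf1 at 0.85 (nearest 0.44), all on replicate 1.

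On replicate 7, the median of the Schwann cell and nerve list was 1.47 (nearest 0.14), with Plp1 at 3.86 (nearest 0.57). The cholesterol synthesis median was 1.42 on the same array (nearest 0.08), with Hmgcs1 at 2.74 (nearest 0.49) and Fdft1 at 1.42 (nearest 0.48). Replicate 3 stood apart in erythroid genes, with a list median of -2.70 (nearest -0.21), Alas2 at -3.13 (nearest -0.21) and Hba-a1 at -2.58 (nearest -0.27), the latter saturated on 3 arrays, among them the control channel of replicate 3. Dbp was at 0.024 on replicate 6 and at -0.61 or lower on the other arrays. Kcnk3 was at -0.70 on replicate 4 and above 0 on the other arrays.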

How the results depend on the processing

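Of the 34 alternatives, 4 were chosen only after results had been seen: local backgrounds as deposited, the control-mouse correlation fixed at 0.5, leaving out replicates 1 and 7, which stand apart in muscle or nerve genes, and leaving out features saturated on any array. The count of genes past the adjusted threshold was 0 with limma in all 34. The count at an unadjusted p under 0.05 was 1991, and it was 3333 with arrays that share a control mouse averaged, 1262 within slide 1, 4377 within slide 2, 943 with median centring without loess, 770 with the fixed correlation, 1113 without replicates 1 and 7, and between 1242 and 2704 with each replicate left out. The averaging over shared control mice weighted each mouse by its arrays and took the dye effect out beforehand. It thus kept the main ratios by construction, and its counts do not check the reuse of control mice. Of the 16 list calls, 3 were kept in all 34 alternatives: collagens (medians from -0.54 to -0.18), interferon response (-0.23 to -0.09) and fatty acid oxidation (0.10 to 0.97). These 3 too were lost with an estimated correlation between genes (adjusted p = 0.538 for each) and with fry. The number of lists called was 7 without replicates 1 and 7, between 12 and 22 with each replicate left out, 19 with local backgrounds as deposited, and 15 without features saturated on any array, where matrix proteases were lost (-0.054). All 20 named genes and 90 of 107 list members kept their sign in the alternatives that gave them a value. These genes were picked from the same data, the 20 for a steady sign and the list members for a small p. A kept sign is therefore no independent support. Another scaling moved the median of all features from 0.012 to -0.016 at most. Signal over background limited the dim genes, and with both channels above background on all 8 arrays 16 lists were called.

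Among single genes and the lists that passed here or in the alternative, these values reversed, and the cause was not tested. Within slide 1 replicate 5 weighed as much as the other arrays together, and within slide 2 replicate 1 did. Within slide 1: the lists of matrix proteases (0.013) and chemokines (0.33), Zap70 (0.014), Pou2af1 (0.087), S100b (-0.17), Idi1 (-0.15), Cyba (0.0050), Nox1 (-0.14), Rac2 (0.051), Npr1 (0.019), Rps3 (0.037) and Rpl27 (0.0044). Within slide 2, the endothelial list was at 0.064. With median centring without loess, Gsn was at -0.11, Gpx4 at -0.013, Ndufb5 at -0.016 and Rpl7 at -0.13. With the mean of all probes of a gene, Rpl7 was at -0.0047 and Rps3 at 0.0071. With each replicate left out, the brown adipocyte median lay between 0.020 (without replicate 1, opposite direction in the test) and 0.70, and Pou2af1 between -0.22 and 0.026. Without the 3 arrays of control mouse K25, matrix proteases were at 0.060, chemokines at 0.17, Zap70 at 0.0091, Fcmr at 0.017, Pou2af1 at 0.088, Alas2 at -0.10, Slc4a1 at -0.11 and Rac2 at 0.041. Without replicates 1 and 7, matrix proteases were at 0.054, brown adipocytes at -0.017, Pou2af1 at 0.015, Idi1 at -0.060, Cyba at 0.054 and Rac2 at 0.094. The ribosomal protein median went from 0.016 to -0.072 with the processed signals or the authors' value table and to -0.21 with median centring without loess. Medians of lists that passed in neither also crossed 0, among them macrophages (0.20 within slide 1, 0.057 without replicate 1) and chemokines (0.16 without replicate 1).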

Other observations

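These tests were chosen only after the result they bear on was seen: the swap of dyes or mice and the control mouse for the macrophage genes, the other probes of the bright features, and the splits for the count of adjusted genes.

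Myh6, the cardiac myosin heavy chain gene, was highest in the 2 channels of replicate 1. It had a log2 level of 15.78 in the DHA channel of replicate 1, where it was saturated, so that this is a lower bound, and 10.74 in the control channel of that array. The same control mouse stood at 6.32 and 6.26 on replicates 2 and 8, and the DHA channels of the other arrays ranged from 6.12 to 8.29. Whether the control value came from that mouse's RNA or from the bright DHA channel of the same spot was not tested. Mapt, which encodes the neuronal protein tau, had its highest level, 12.19, in the DHA channel of replicate 7, where Plp1 was at 10.49.

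The macrophage list ran from a median of -2.13 to 1.92 on single arrays. A swap of dyes or mice on the array pairs 1 and 2 or 5 and 7 is argued against, since the channels labelled as the shared control mouse correlated with each other by at least 0.53 more than any other pairing. The labels of replicate 8 were less clear: its control channel correlated with that of replicate 2 at 0.94 (its DHA channel at 0.84), but with that of replicate 1 at 0.77 (its DHA channel at 0.80). In each comparison the higher value was between 2 channels of the same dye. Neither therefore decides on the labels of replicate 8. The control mouse alone is argued against by replicates 5 and 7, which share a control mouse and passed the label test, since their list medians differed by 2.70 ± 0.25 (SE over list genes) while the list genes differed by 0.02 in the control channels and by 3.14 in the DHA channels. Replicates 2 and 8, with the same control mouse, dye and slide, differed by 2.89 ± 0.32 as labelled and by 1.36 ± 0.27 with replicate 8 turned, and replicates 1 and 2 by 0.64. Control mice contributed as well, since the list level of the control channel repeated within a mouse and differed between mice. It was 11.2, 11.54 and 11.62 for K25, and 10.36 and 10.34 for K93. The control mice on replicates 3, 4 and 6 stood at 9.42, 8.02 and 8.63. Replicate 6 had the highest list median, yet its DHA level (10.81) was below those of K25. The size of the control mice's part was not measured. A different share of macrophages in each piece of aorta may account for the range of medians. Over the 8 arrays, 20 macrophage genes outside the list followed the list median with a median r of 0.94. Genes within the list varied together as well (estimated correlation 0.83). This does not tell a share of macrophages apart from expression per cell or from the control mice. Whether such a share follows plaque, dissection or diet was not tested.

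A set of 61 bright features, 14 of them with symbols such as Dcc, Pigr and Gcm1, was picked by its close correlation with Dcc over the arrays. It moved together with a median log2 ratio of 1.07 and was above 0 on 7 of 8 arrays (smallest adjusted p = 0.590, limma). The RNA of the genes they are named after stays open. The 12 other probes of 9 of these genes followed the bright probe with a median r of 0.35, but most were dim (median log2 intensity 6.92 against 12.81), and of the 3 bright ones the 2 of Gcm1 had r of 0.957 and 0.998 and that of Rgs7bp -0.134. The particular background correction and loess used here are argued against, since the median ratio with the scanner software's own signals was 0.956 of that reported. Those signals were dye-normalized as well, so that a fault common to both treatments was not tested. Dye bias cannot be told apart from the rest, because the dye term was 0.621 of the DHA term, between the bounds set for it. What these probes bind stays open, and no biological explanation was tested.

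The fatty acid oxidation list was higher with DHA on 7 arrays as labelled (0.23 on replicate 8, whose labels were less clear) and followed the fat cell lists. Fat attached to the aorta may account for its shift: where the fat cell lists are at 0, the fitted median of the list was 0.12 ± 0.09 (SE), within 2 standard errors of 0. The fatty acid oxidation median was highest on replicate 1 (1.29), where the muscle list also stood highest (1.46). These 2 lists were not set against each other, so that fat cannot be told apart from muscle tissue on that array. A change within the vessel wall or within fat cells stays open and was not tested, and 3 of the 8 arrays share a control mouse.

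A hypothesis from Tsc22d3, Cebpb, Pdk4 and Angptl4 is a glucocorticoid-type response in the DHA aortas. Of 14 other responsive genes listed before the test, 12 had a ratio above 0, with a median of 0.30, including the metallothionein gene Mt2 at 0.92 ± 0.24, Fkbp5 at 0.86 ± 0.30 and Mt1 at 0.67 ± 0.21, none of which passed over all genes. The list gave p = 8.94e-04 with camera at the preset correlation, p = 0.141 with an estimated correlation and p = 0.0634 with fry, so that the data leave it open. A different clock phase, from Dbp and Nr1d1, was tested on 7 other genes of the Dbp phase against Arntl, Npas2 and Clock. Their difference was -0.087 ± 0.103 (SE), below 0 on 4 of 8 arrays (exact two-sided sign-flip p = 0.43), which decides nothing.

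Other splits of the 8 arrays into 5 and 3, over the 24965 features with a value on all arrays, showed whether chance can be excluded. For the adjusted genes this decides nothing, since with 0 in the real split all 56 of 56 must give at least as many (at most 1 in another). It cannot be excluded for the other counts. At least as many genes with an unadjusted p under 0.05 were found in 8 of 56 (1983, against a median of 861 and at most 3050 in the other splits). At least as many lists were found in 21 of 56 (16, against a median of 13 and at most 24).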
